A study of Mus musculus with 8 samples.

How the data were processed

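Tregs were flow-sorted from mouse spleen, and total RNA was made into dual-indexed, strand-specific libraries with a low-input total RNA kit, per the labels' protocols. Each of the 8 libraries is a column of 1 deposited table, 4 labelled IL-2 and 4 labelled control. Columns were matched to samples by the library number in the labels. The gating used for the sort, the number of animals and the dosing of these samples are not given in the sources used here.

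The values are variance-stabilised expression on a log2 scale, deposited by the authors under the name of a DESeq2 transformation. Salmon, DESeq2 and the genome build GRCm39 are named in the submitters' processing notes, without their order or settings. The annotation and any filter the authors applied are not given in the sources used here. Salmon divides reads that match several transcripts among them by estimation, so values of near-identical genes, such as histone, guanylate-binding protein and ribosomal protein genes, are uncertain. No coordinates are given, because the annotation at hand was of another build.

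The table holds 21524 genes with a lowest value of 8.69 shared by every library and standing for 0 reads. Normalised read counts were recovered with the inverse of the parametric variance-stabilising formula of the authors' tool, whose scale is fixed by the lowest value. This was checked on the 5 commonest values just above the lowest in each library: 36 of the 40 came out as whole multiples of 1 read within 0.001, and the recovered size factors had a geometric mean of 1. Most other genes did not give whole reads, as estimated counts need not, so no count test was run. The recovered totals put depth at 4953541 to 6399417 reads per library. The scale is compressed near the lowest value: 1 unit above it corresponds to 206 normalised reads, where counting error alone gives a coefficient of variation of 6.96%, and 2 units to 928. Differences on the deposited scale therefore understate fold changes, most of all of genes with few reads. Folds in the text are ratios of group means of normalised read counts. The main filter left out genes at a few reads, so a fall in them was not tested in the main fit. Many such falls could be missed at this depth.

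The main test was fixed from the labels before the data were examined. Genes were kept when at least 4 of the 8 libraries lay at least 1 above the lowest value, which left 5261. The deposited values, IL-2 minus control, were fitted with limma (lmFit, eBayes with trend), without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. There were 31 gene lists, also fixed in advance, for Treg states, cytokine responses, helper subsets, metabolism, sample quality and 10 other cell types. Lists with at least 5 tested genes, 20 in all, were tested with camera at its preset inter-gene correlation of 0.01 and adjusted over lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, while fry asks only whether a list's genes move on balance 1 way. Summed normalised read counts of lists were compared with two-sided exact permutation tests over 70 splits, whose smallest p is 0.0286.

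Genes named in the text followed a rule fixed in advance. It took 16 genes of IL-2 signalling and Treg states, the 12 largest rises and the 12 largest falls among genes past the threshold with groups that did not overlap and a mean at or above the median of tested genes, leaving out predicted genes and receptor segments, and up to 4 members of each list with the smallest adjusted p in the list's own direction. Some genes that the rule took are not reported here. Members of a list named beyond that, such as those that went against the rest, and the genes named only in the closing section were chosen after their values were seen.

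Alternatives planned in advance were no filter, a stricter filter of 2 above the lowest value, quantile normalization, centring each library on its median, limma without trend, with robust fitting and with array weights, leaving out each library in turn on the same 5261 genes, camera with an estimated correlation, fry, and lists without shared genes. Leaving out libraries was first run with the filter applied anew, which removed genes present only in the IL-2 group; keeping the same genes was decided after seeing this. Also chosen after seeing the data were a limma fit on log2 of normalised reads plus 5 for genes with at least 10 such reads in at least 4 libraries (10777 genes), a fit with the presence of the Y-linked transcript Ddx3y as a covariate, and an exact permutation test of list means. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

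The limma step was tested on simulated values for the 5261 genes of the IL-2 and control comparison, with 200 genes changed. It recovered 46% of genes changed by 0.25, 98% at 0.5, 98% at 1 and 100% at 1.5 on the deposited scale, and called 11 of 5061 unchanged genes. Spearman correlations across genes ran from 0.959 to 0.963 within groups and from 0.946 to 0.954 between groups, and no 2 libraries held the same values. Length and GC content per gene came from transcripts matched by symbol, which covered 96.8% of tested genes.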

Results

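RNA was sequenced from regulatory T cells (Tregs) sorted by flow cytometry from mouse spleen. Tregs are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The labels gave 4 libraries the treatment IL-2 (replicates 41 to 44) and 4 libraries the treatment control (replicates 45 to 48). IL-2 is the cytokine that Tregs need for survival, and its high-affinity receptor contains the chain encoded by Il2ra. The text that accompanies the series describes a modified IL-2 given to recipients of mismatched hearts or kidneys together with CTLA-4 Ig, a blocker of T cell co-stimulation, and asks how Tregs act and what role their ST2-positive subset plays. The labels did not say whether the IL-2 group received this modified IL-2 or the unmodified cytokine, or whether either group received CTLA-4 Ig. They also did not say what the control animals received or whether these animals carried a graft. Whether each library came from a separate animal was not given either, so the p-values measure the spread between these libraries.

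The deposited table held 1 variance-stabilised value per gene and library for 21524 gene symbols. Its lowest value stood for 0 reads and was shared by 6620 genes in all 8 libraries. Normalised read counts were recovered from the values, as described under processing, and are given below as mean ± SD with n = 4 per group. Estimated depth ran from 4953541 to 6399417 reads per library in the IL-2 group and from 4970816 to 6147508 in the control group. Between 12302 and 12688 genes had a value above the lowest in a library. The first principal component of the tested genes held 61.3% of the variance and placed all 4 IL-2 libraries on 1 side and all 4 control libraries on the other.

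The comparison of IL-2 with control libraries asked which transcripts of splenic Tregs differed under the treatment. The transcripts of the IL-2 receptor chains Il2ra and Il2rb, of the feedback inhibitors Cish, Socs1 and Socs2 and of granzyme B rose. The related inhibitor gene Socs3 did not pass (limma adjusted p = 0.108). A rise was also seen in most tested genes of DNA replication and mitosis and of ribosomal proteins. These lists no longer passed with an estimated correlation (adjusted p = 0.116 and 0.176). Most tested genes of follicular T cells, of chemokine receptors and homing and of the response to interferon fell, of which the homing list still passed with an estimated correlation (adjusted p = 0.0262) and the follicular and interferon lists did not (adjusted p = 0.116 and 0.320). Foxp3 and Ctla4 did not pass the test. Of 5261 genes tested with limma, 1650 (31.4%) passed an adjusted p of 0.05, of which 883 were higher and 767 lower with IL-2. A difference of at least 1 on the deposited log2 scale was reached by 36 of them, 26 higher and 10 lower. That scale is compressed: fitted on log2 normalised read counts, 222 of the same 5261 genes passed with at least a 2-fold difference, 141 higher and 81 lower. That fit also took in genes with fewer reads, 10777 in all, among which 430 were at least 2-fold higher and 309 at least 2-fold lower. The 4 IL-2 libraries lay wholly above or wholly below the 4 control libraries for 1655 tested genes (31.5%), where chance gives 2.86%.

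**Figure D1:**
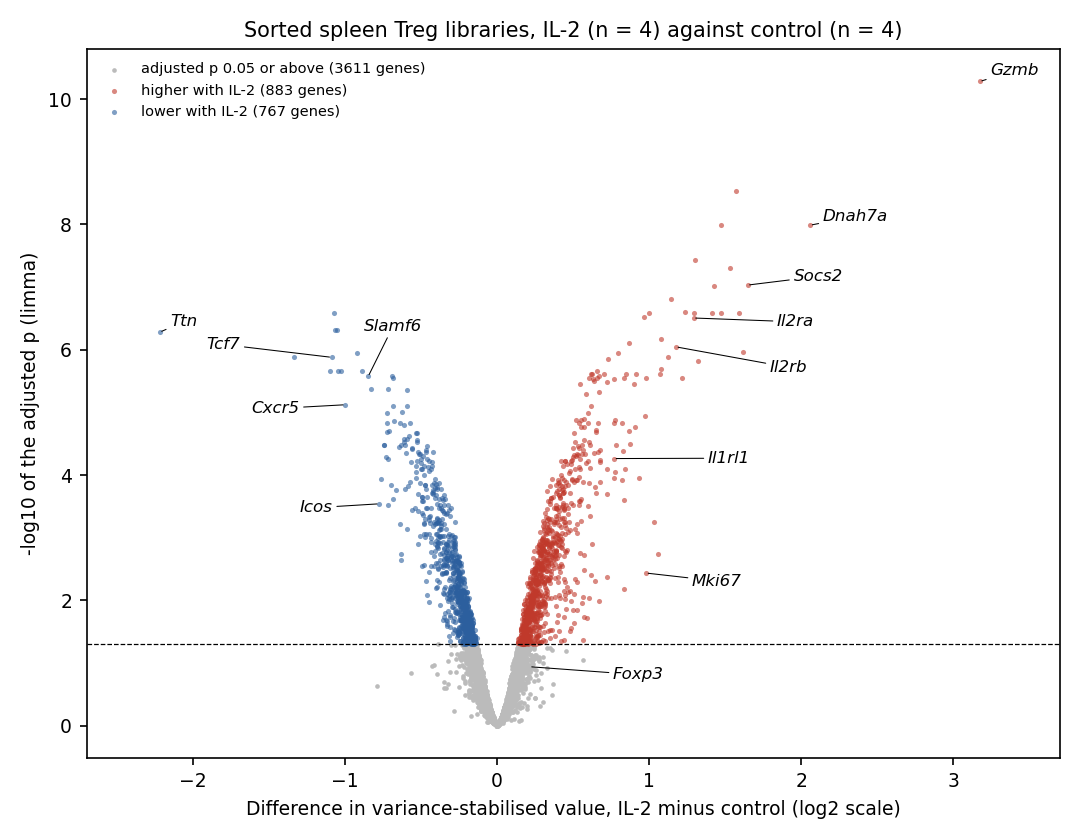
Each point is 1 of 5261 tested genes, with the difference in variance-stabilised value (IL-2 minus control, log2 scale) on the x axis and -log10 of the limma adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, above which 883 genes were higher (red) and 767 lower (blue) with IL-2, Gzmb rising most.

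Among the well-measured genes whose groups did not overlap, Gzmb had the largest rise on the deposited scale. Gzmb encodes granzyme B, a protease of cytotoxic granules, and its normalised read count was 9083 ± 623 with IL-2 against 429 ± 91.6 in controls, 21.2-fold higher (limma log2 difference 3.17 ± 0.08 SE, adjusted p = 5.21e-11). Dnah7a, a dynein heavy chain gene of cilia, was next with 2044 ± 264 against 104 ± 46.2. Socs2, an inhibitor of JAK-STAT signalling, reached 2084 ± 319 against 271 ± 57.5, 7.69-fold higher. Pcyt1a, whose enzyme makes the CDP-choline used for phosphatidylcholine, was 9.25-fold higher. The phosphatase genes Ppm1l and Ptpn9 were 6.14-fold and 6.20-fold higher. Elovl6, a fatty acid elongase, rose 4.54-fold, Itih5, of the inter-alpha-trypsin inhibitor family, 3.41-fold, and Vim, which encodes the filament protein vimentin, 3.13-fold. Lrrc32, whose product GARP holds latent TGF-beta at the Treg surface, rose 2.66-fold. Il2ra and Il2rb completed the 12 largest rises.

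Among the same well-measured genes, the largest fall on the deposited scale was that of Ttn, the gene of the giant protein titin, from 14578 ± 2493 normalised reads in controls to 2557 ± 662 with IL-2, 5.70-fold lower (limma log2 difference -2.22 ± 0.15 SE, adjusted p = 5.24e-07). The transcription factor genes Rora, Tcf7 and Maf were among those that followed, Rora 4.49-fold and Maf 2.68-fold lower. Tcf7 went from 2584 ± 298 to 862 ± 139. Cmah, which encodes a sialic acid hydroxylase, and the growth factor receptor gene Igf1r were 3.14-fold and 3.02-fold lower. The surface receptor genes Slamf6 and Icos fell 2.64-fold and 2.36-fold. Slc4a7, a bicarbonate transporter, Iigp1, an interferon-inducible GTPase, and Actn1, an actin crosslinker, fell 2.53-fold, 2.52-fold and 2.56-fold.

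Genes known to respond to IL-2 through STAT5 mostly rose. Of 22 tested members of that list, 16 rose and 3 fell (16 and 5 adjusted over the list alone). Il2ra went from 6935 ± 781 normalised reads to 18107 ± 1601 (adjusted p = 3.11e-07), Il2rb from 5377 ± 449 to 13183 ± 1489 (adjusted p = 8.99e-07) and Cish, another inhibitor of the pathway, from 230 ± 29.6 to 826 ± 127 (adjusted p = 2.47e-06, all limma). Il2rb was lower in IL-2 library 44 than in the other 3 IL-2 libraries. The survival gene Bcl2 (4683 ± 717 against 2310 ± 279) and Myc (921 ± 171 against 367 ± 57.5) also rose. The 3 members that fell were Stat5b, Jak3 and Prdm1, of which Stat5b, a signal transducer of the pathway itself, went from 2232 ± 128 to 1422 ± 67.6. The list passed camera (adjusted p = 1.88e-06), with an adjusted p = 0.143 with an estimated correlation.

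Among Treg identity genes, 8 of 16 tested rose and 1 fell (8 and 3 adjusted over the list alone). Il2ra, Lrrc32, Socs2 and Capg had the smallest p, Capg with 1453 ± 81.1 against 835 ± 93.9. Tnfrsf18, which encodes the receptor GITR, rose from 1327 ± 154 to 2246 ± 303, and Nrp1 was the gene that fell, from 1600 ± 93.2 to 996 ± 324. Foxp3 stood at 1883 ± 262 normalised reads with IL-2 and 1537 ± 290 in controls (limma adjusted p = 0.115, 95% interval of the log2 difference 0.00 to 0.42 before adjustment). Ctla4, an inhibitory receptor gene, stood at 3888 ± 882 and 3860 ± 1023 (adjusted p = 0.950), and Ikzf2, which encodes the Treg factor Helios, at 10602 ± 847 and 10224 ± 608 (adjusted p = 0.629). The list passed camera (adjusted p = 0.00202), with an adjusted p = 0.143 with an estimated correlation and an adjusted p of 0.0972 without the genes it shares with other lists.

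ST2, the receptor for IL-33, is encoded by Il1rl1. Its normalised read count was 1243 ± 232 with IL-2 and 484 ± 107 in controls, 2.57-fold higher (limma log2 difference 0.77 ± 0.09 SE, adjusted p = 5.45e-05), and all 4 IL-2 libraries lay above all 4 controls. Gene-level values do not separate the membrane-bound from the secreted form. Other genes of ST2-positive tissue Tregs went both ways: of 14 tested, 3 rose and 7 fell (4 and 8 adjusted over the list alone). Besides Il1rl1, Cd200r1 (615 ± 116 against 251 ± 39.7) and Tnfrsf9 rose. The genes that fell with the smallest p were Rora (273 ± 41.4 against 1226 ± 256), Ccr4, Ccr2 and Pdcd1, where Ccr4 and Ccr2 encode chemokine receptors and Pdcd1 the inhibitory receptor PD-1. Gata3, a transcription factor of this subset, stood at 1197 ± 135 and 1034 ± 194 (adjusted p = 0.232). Klrg1 stood at 524 ± 113 and 393 ± 79.5 (adjusted p = 0.105) and passed without IL-2 library 42 (adjusted p = 0.0184). Areg, the gene of the repair factor amphiregulin, had 25.7 ± 21.1 and 34.4 ± 21.8 normalised reads, and Il10 had 60.5 ± 26.4 and 46.2 ± 18.9, both too few for the filter of the limma fit. Their two-sided exact permutation p-values were 0.514 and 0.457. The list did not pass camera (adjusted p = 0.0876), but did without control library 46, as a fall (adjusted p = 0.0419). It also passed fry, as a fall (adjusted p = 0.0185).

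**Figure D2:**
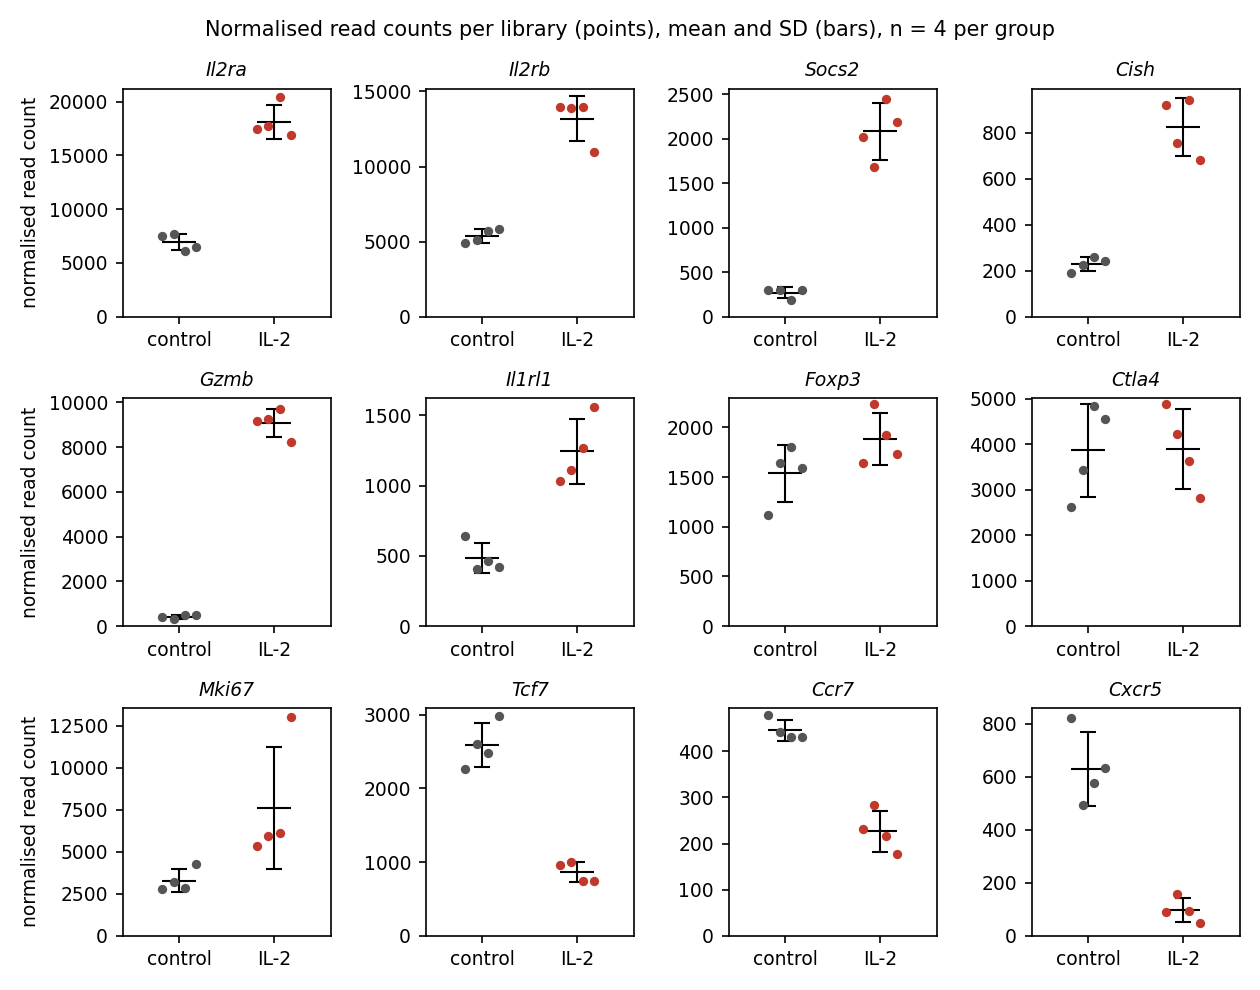
Normalised read counts (y axis, from 0) of 12 genes in the 4 control and 4 IL-2 libraries (x axis), 1 point per library, with bars for mean and SD. Il2ra, Il2rb, Socs2, Cish, Gzmb, Il1rl1 and Mki67 were higher and Tcf7, Ccr7 and Cxcr5 lower in all 4 IL-2 libraries, while Foxp3 and Ctla4 overlapped, and Mki67 was highest in library 44 at 13044.

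For the 16 genes fixed in advance, an exact two-sided permutation test over 70 splits was run beside limma. Il1rl1, Il2ra, Il2rb, Cish, Socs2, Mki67, Ccr7 and Tcf7 had an exact p = 0.0286, the smallest that 4 against 4 libraries can give, and 0.0571 after adjustment over the 16 genes. The other 8 had p-values from 0.143 to 0.943.

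Molecules of effector and suppressive Tregs also split. Of 16 tested, 6 rose and 8 fell (6 and 9 adjusted over the list alone). Gzmb, Lgals1 (1886 ± 412 against 698 ± 56.0), which encodes galectin-1, and Tgfb1 (1234 ± 99.4 against 707 ± 68.9) rose. Maf, Icos, Pdcd1 (116 ± 8.46 against 398 ± 78.8) and the adhesion molecule gene Cd44 (758 ± 115 against 1200 ± 70.7) had the smallest p among those that fell. Prdm1, at 329 ± 40.6 against 565 ± 203, no longer passed without IL-2 library 41 (adjusted p = 0.0502). The median difference of the list was -0.22 and its mean 0.12, camera placed it on the lower side (adjusted p = 0.695) and fry on the higher side (adjusted p = 0.0219).

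Genes of resting Tregs and naive T cells gave 4 rises and 7 falls among 17 tested (4 and 7 adjusted over the list alone). Tcf7 fell from 2584 ± 298 to 862 ± 139, Satb1, a chromatin organiser, from 2860 ± 302 to 1522 ± 112 and Ccr7, the receptor for lymph node entry, from 446 ± 22.7 to 227 ± 44.5 (limma adjusted p = 1.32e-06, 1.37e-05 and 2.94e-04). Igfbp4 rose, from 226 ± 52.7 to 926 ± 290. The list did not pass camera (adjusted p = 0.0876), but did without control library 45, as a fall (adjusted p = 0.0381). It also passed camera without a filter (adjusted p = 0.020) and on log2 normalised reads (adjusted p = 0.0275), and passed fry (adjusted p = 0.0166).

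Follicular genes had the lowest median of the tested lists, -0.62. Of 8 tested, 7 fell and 0 rose (7 and 0 adjusted over the list alone). Bcl6, the lineage factor of follicular T cells, went from 330 ± 54.4 normalised reads to 75.0 ± 11.7, and Cxcr5, their chemokine receptor, from 630 ± 139 to 96.5 ± 44.0, 6.53-fold lower (limma adjusted p = 1.46e-05 and 7.54e-06). Slamf6 and Pdcd1 were also among the 4 smallest p. The list passed camera (adjusted p = 6.89e-07), with an adjusted p = 0.116 with an estimated correlation. B cell markers moved with this list: their summed normalised read count was 185 ± 47.0 with IL-2 and 615 ± 53.9 in controls (exact permutation p = 0.0286), of which Cd74 made up 88.5 ± 40.1 and 396 ± 35.4.

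Chemokine receptors and homing molecules fell in 11 and rose in 2 of 18 tested (11 and 2 adjusted over the list alone). Besides Cxcr5, Ccr4 (log2 difference -0.58, adjusted p = 1.46e-05), Ccr2 (339 ± 70.6 against 917 ± 134) and the integrin gene Itgb1 (1380 ± 149 against 2394 ± 118) had the smallest p. Selplg and Itgb7 rose, Itgb7 from 3093 ± 318 to 4308 ± 468. This list passed camera with the preset (adjusted p = 1.73e-05) and with an estimated correlation (adjusted p = 0.0262), but not with the stricter filter on low values (adjusted p = 0.326).

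Genes of type 1 helper cells fell in 6 of 7 tested, with 0 rising (6 and 0 adjusted over the list alone). Cxcr3 (161 ± 28.4 against 424 ± 44.9) and Il27ra were among them, and the list passed camera with the preset (adjusted p = 3.79e-05) and with an estimated correlation (adjusted p = 0.0277). The interferon response list fell in 6 of 10 tested, with 0 rising (7 and 1 adjusted over the list alone). Ifit2 (375 ± 32.7 against 645 ± 94.1), Irf9 (629 ± 89.2 against 973 ± 71.1) and Stat2, which acts with Irf9 downstream of the type I interferon receptor, were among them. That list passed camera (adjusted p = 0.00302), with an adjusted p = 0.320 with an estimated correlation. Markers of monocytes, macrophages and dendritic cells moved the same way, from a summed normalised read count of 2154 ± 131 in controls to 1238 ± 117 (exact permutation p = 0.0286), of which the protease gene Ctss made up 1663 ± 140 and 847 ± 121.

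Type 17 genes numbered 4 in the tested set, too few for camera. Rora, Maf and Stat3 (1589 ± 182 against 2139 ± 244) fell, and Batf stood at 345 ± 60.3 and 462 ± 74.4 (limma adjusted p = 0.0594). All 4 fell when adjusted over the list alone. On log2 normalised reads 7 members were tested, of which 6 fell and 0 rose, and the list passed camera as a fall (adjusted p = 6.63e-07). Type 2 genes numbered 5, of which Il1rl1 and Il4ra rose and Ccr4 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.557). The type 2 list passed the exact permutation of list means (adjusted p = 0.044). The transcript of the type 2 cytokine Il5 had fewer than 1 normalised read on average in either group.

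T cell receptor activation genes fell in 7 and rose in 2 of 20 tested (7 and 2 adjusted over the list alone). Icos, Cd44, Cd5 (2236 ± 54.5 against 2778 ± 130) and Irf4 had the smallest p, and Cd69 and Tnfrsf9 rose. The list passed camera (adjusted p = 0.00837), with an adjusted p = 0.320 with an estimated correlation and an adjusted p of 0.0598 with the stricter filter. The TNF receptor family and NF-kB list gave 4 rises and 7 falls among 18 (4 and 7 adjusted over the list alone, camera adjusted p = 0.182). It passed as a fall without the genes it shares with other lists (adjusted p = 0.0105), without a filter on low values (adjusted p = 0.0442) and on log2 normalised reads (adjusted p = 0.0442). Tnfrsf18, Tnfrsf4 and Tnfrsf9 rose, while Icam1 (263 ± 38.2 against 589 ± 60.9), Tnfrsf1b, Birc3 and Relb fell.

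**Figure D3:**
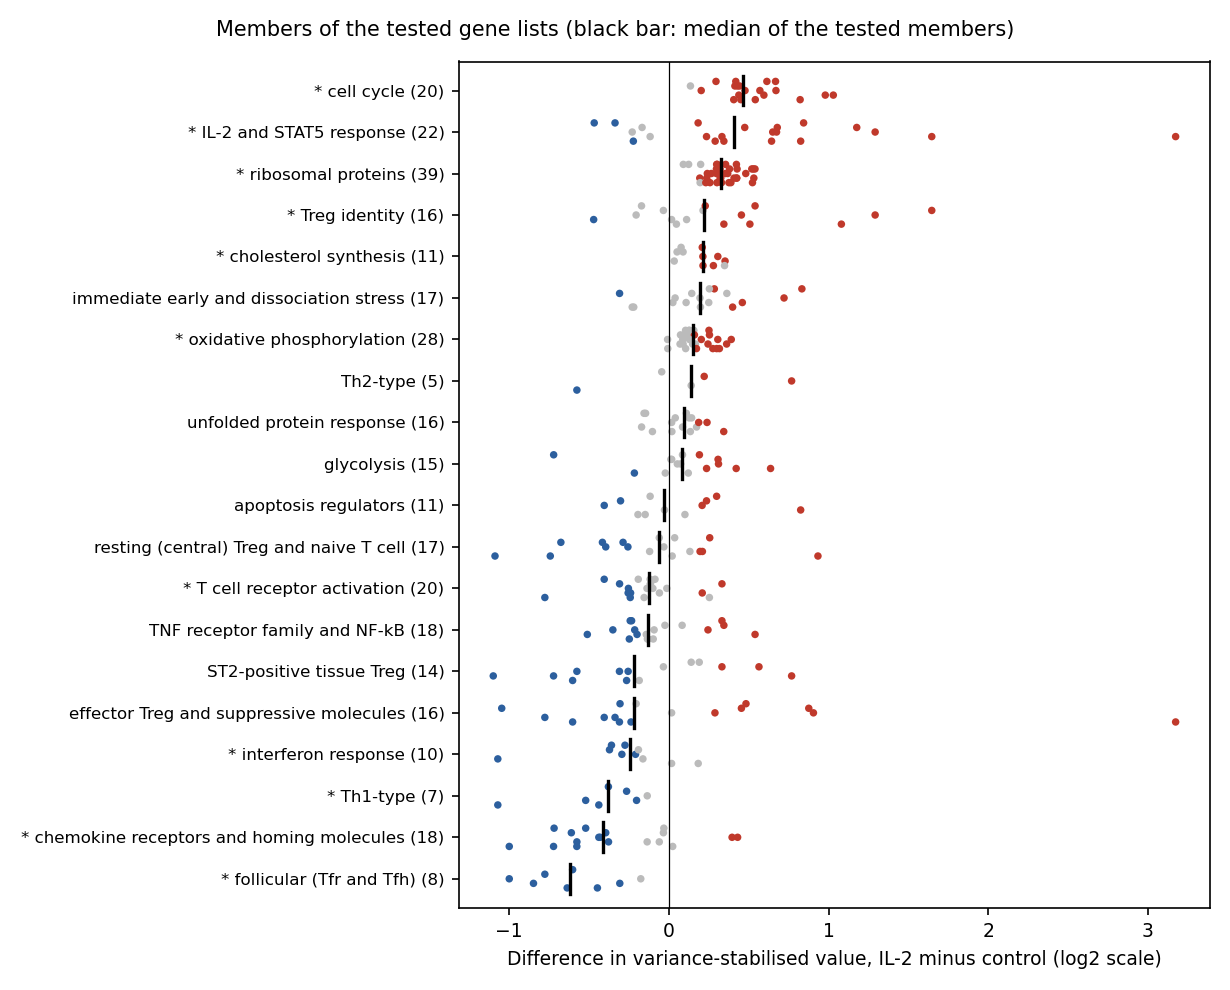
Each row is 1 gene list with its number of tested members, each point is 1 member placed by its difference in variance-stabilised value (IL-2 minus control, log2 scale, x axis), and the black bar is the median. Red and blue members passed an adjusted p of 0.05, grey members did not, and an asterisk marks the 11 lists that passed camera with the preset correlation, from cell cycle (median 0.46) to follicular (median -0.62).

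Cell cycle genes rose in 19 of 20 tested, with 0 falling (19 and 0 adjusted over the list alone). Uhrf1 (706 ± 52.3 against 256 ± 43.0), Mcm3, Mcm7 and Pcna (982 ± 113 against 539 ± 41.4), which act in DNA replication and its upkeep of methylation, had the smallest p. Mki67, the gene of the proliferation marker Ki-67, stood at 7614 ± 3637 with IL-2 and 3284 ± 682 in controls (limma adjusted p = 0.00367). Library 44 held 13044 reads of Mki67 and the other IL-2 libraries 5332 to 6142. Without it, Mki67 still passed (adjusted p = 4.11e-04) and 19 of the 20 genes still rose. The list passed camera (adjusted p = 8.95e-11), with an adjusted p = 0.116 with an estimated correlation.

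Ribosomal protein genes rose in 35 of 39 tested, with 0 falling (38 and 0 adjusted over the list alone), by a median of 0.32. Rps2 (4781 ± 225 against 3106 ± 53.2), Rpl32, Rpl3 and Rplp0 (12290 ± 745 against 8276 ± 516) had the smallest p. These genes have many processed copies in the genome that can share reads. Ribosomal protein transcripts made up 5.78% ± 0.337 of the recovered reads in the IL-2 libraries and 4.56% ± 0.262 in controls (SD, n = 4 each). Other shares of the reads also differed without overlap: mitochondrial mRNA made up a mean of 1.73% with IL-2 and 1.53% in controls, and the 10 most abundant genes 4.65% to 4.92% and 4.10% to 4.27%. The list passed camera (adjusted p = 5.59e-15), with an adjusted p = 0.176 with an estimated correlation.

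Oxidative phosphorylation genes rose in 12 of 28, with 0 falling (13 and 0 adjusted over the list alone). The ATP synthase genes Atp5f1b (2322 ± 47.7 against 1652 ± 44.5) and Atp5f1a, the cytochrome c gene Cycs (478 ± 61.0 against 249 ± 28.1) and Cox5b led. This list passed camera with the preset (adjusted p = 6.68e-06) and with an estimated correlation (adjusted p = 0.0262), but not with the stricter filter on low values (adjusted p = 0.0515). Cholesterol synthesis genes rose in 6 of 11, with 0 falling (7 and 0 adjusted over the list alone), among them Idi1 and Cyp51. That list passed camera (adjusted p = 0.00341), with an adjusted p = 0.320 with an estimated correlation. Glycolysis genes rose in 6 and fell in 2 of 15 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0563). Eno1 (3867 ± 157 against 2226 ± 128), Ldha, Gpi1 and Gapdh rose, and Hif1a, the hypoxia factor, and Aldoa fell. The glycolysis list passed without IL-2 library 44 (adjusted p = 0.0409). It also passed camera without a filter, without shared genes and on log2 normalised reads (adjusted p = 0.0208, 0.0478 and 0.0447). Fry and the exact permutation of list means passed it too (adjusted p = 5.67e-04 and 0.044).

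Apoptosis regulators rose in 4 and fell in 2 of 11 (4 and 3 adjusted over the list alone, camera adjusted p = 0.879). Bcl2, Bcl2l1, Bcl2l11 and Casp8 rose, and Cflar and Bcl2a1b fell, the last a gene with near-identical copies. The median of the list was -0.03, its mean 0.04 and its camera direction upward. In this list Apaf1 stood at 406 ± 81.8 and 538 ± 73.7 (limma adjusted p = 0.0522) and passed without IL-2 library 44 (adjusted p = 0.00981), as did Xiap (982 ± 154 against 1150 ± 37.3, adjusted p = 0.0215 without it). Of 16 tested genes of the unfolded protein response, Xbp1 (542 ± 42.4 against 320 ± 47.9), Hsp90b1 and Pdia4 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.182). That list passed fry, as a rise (adjusted p = 0.0183). Hsp90b1 and Pdia4 no longer passed without control library 46 (adjusted p = 0.0525 and 0.0532), Hsp90b1 also not with quantile normalization (adjusted p = 0.0503), and Canx, at 2058 ± 109 and 1801 ± 145, passed without control library 45 (adjusted p = 0.0337).

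Immediate early and dissociation stress genes rose in 5 and fell in 1 of 17 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0876). Hspa8 (18981 ± 3093 against 11101 ± 840), Hsp90aa1, Hsp90ab1 and Fos rose, Fos with groups that overlapped (699 ± 349 against 186 ± 159), Ier2 also rose, and Egr1 fell. Fos did not pass with robust fitting (adjusted p = 0.0538). The list passed as a rise without IL-2 library 41, without IL-2 library 44 and without control library 47 (adjusted p = 0.00655, 0.0395 and 0.0228). It also passed camera without a filter, on log2 normalised reads and without the genes it shares with other lists (adjusted p = 0.0208, 0.0250 and 0.0247).

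Markers of other cell types were low, and few passed the filter on low values. Their summed normalised read counts were compared with exact permutation tests. Cd79a and Ms4a1, which B cells hold at high levels, had fewer than 3 normalised reads on average in each group. NK cell markers summed to 112 ± 21.4 with IL-2 and 175 ± 36.3 in controls (exact p = 0.0286), CD8 T cell markers to 89.8 ± 24.8 and 151 ± 26.9 (p = 0.0571), and neutrophil markers to 227 ± 26.9 and 168 ± 15.3 (p = 0.0571). Erythroid markers summed to 794 ± 134 and 474 ± 102 (exact p = 0.0286), of which Tfrc, the transferrin receptor gene that dividing T cells also express, made up 767 ± 123 and 412 ± 67.4. Stromal and endothelial markers summed to 1083 ± 79.4 and 1390 ± 111 (exact p = 0.0286), nearly all of it Pecam1, which T cells also express. Plasma cell markers (1622 ± 65.6 and 1745 ± 210, exact p = 0.400), platelet and megakaryocyte markers (720 ± 167 and 669 ± 108, p = 0.686, of which Itgb3 made up 648 ± 166 and 616 ± 98.1) and cytokines of conventional CD4 T cells (252 ± 70.4 and 268 ± 31.3, p = 0.686) did not pass. In the last list, members moved both ways: on log2 normalised reads 1 of 4 rose and 1 fell. The latter was the ligand gene Cd40lg, at 53.1 ± 30.6 with IL-2 and 119 ± 22.9 in controls (limma adjusted p = 0.0248), with overlapping groups.

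Camera treats the genes of a list as nearly independent, and 11 of 20 tested lists passed it, 6 as rises and 5 as falls. With the correlation estimated per list, 3 passed: chemokine receptors and homing molecules, type 1 genes and oxidative phosphorylation. Their estimates were -0.0204, -0.0649 and -0.0105 in that order, below the preset of 0.01. Passing therefore does not show that these lists withstood an allowance for correlated genes. Other divisions of the 8 libraries into 4 and 4 gave up to 14 passing lists, so the number of lists by itself does not set the treatment apart from them.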

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

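In 13 of the 206 sets of 4 libraries checked, 1 library lay far from the other 3, where chance gives about 10, so most of these single values need no special reason. The test with Foxp3 was chosen after its result was seen. The other tests were written before their own values were computed, but after other values of these genes had been looked at.

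Library 44 of the IL-2 group was set apart in 4 of the 13. It had 13044 normalised reads of Mki67 where the other 3 had 5332 to 6142, 10949 of Il2rb where they had 13887 to 13962, 445 of Ccr2 where they had 303 to 305, and 2154 of Cd5 where they had 2261 to 2265. The pattern behind the first reached beyond Mki67. Of 19 mitotic genes of the cell cycle list, 18 were highest in library 44 within its group, and their summed normalised count was 2.23 times the mean of the other 3 IL-2 libraries, while 17 replication genes summed to 1.03 times that mean. Transcript length and GC content argue little for this: corrected for both, the median excess of the mitotic genes was 0.40 on the deposited scale against 0.42 before. Dividing cells of most other types were also argued against. The largest excess of any other marker list in library 44 was 168 normalised reads (erythroid markers), against 6902 for Mki67. Conventional CD4 T cells were covered only by 8 cytokine and ligand genes, which dividing cells need not express, so they are not excluded. Ctla4 (2813) and Lrrc32 (3143) were lowest in library 44 within its group, while Foxp3 (1731) and Ikzf2 (11055) were not. The excess was not confined to mitotic genes: histone genes summed to 52761 in library 44 against 25635 to 27827 in the other IL-2 libraries. A larger share of dividing Tregs at the time of sorting in that animal or sample may remain, but nothing in the labels tests it.

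The fall of follicular genes could in principle come from other cells in the control sort. B cells were argued against: the highest control mean among Cd79a, Cd79b and Ms4a1 was 42.0 normalised reads (Cd79b), while the mean of Cxcr5 differed by 534 between the groups, and Cd79b was no lower with IL-2 (60.1 ± 31.1). Conventional follicular helper cells, which lack Foxp3, cannot be told apart from a change within the Tregs, because Foxp3 differed by 0.21 with an adjusted p of 0.115. Cd40lg, of the conventional CD4 T cell list, was lower with IL-2 (53.1 ± 30.6 against 119 ± 22.9), while the sum of that list did not pass (exact permutation p = 0.686). A smaller share of follicular Tregs with IL-2, or lower expression per cell, stays open as a hypothesis, since bulk libraries do not separate them.

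The rise of ribosomal protein genes may have technical sources. After each library was corrected for transcript length and GC content the median rise was 0.26, against 0.32 before, and 27 of 39 genes still passed, against 35. Centring each library on its median left the median at 0.31. The median difference over all tested genes was already -0.008, so centring could move little and does not decide on a scaling difference. A rise in the Tregs stays a hypothesis. Reads shared with processed gene copies and an RNA handling difference between the groups were not tested. Mitochondrial mRNA also took a larger share of reads with IL-2 (a mean of 1.73% against 1.53%).

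The remaining sets held a single library apart, given here as values without explanation. Ikzf2 had 11124 normalised reads in control library 45 and 9793 to 10009 in the other 3. Socs2 had 185 in control library 47 and 297 to 303 in the others. In control library 48, Slc4a7 had 964 reads (1304 to 1360 elsewhere in its group) and Itgb1 2218 (2435 to 2465). Satb1 had 3308 in control library 46 and 2652 to 2739 in the others. Cycs had 387 in IL-2 library 43 and 504 to 512 in the others. In IL-2 library 42, Atp5f1a had 3229 (3063 to 3087), Rpl3 had 11748 (10204 to 10342) and Prdm1 had 389 (304 to 318).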

How the results depend on the processing

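The fit on log2 normalised reads, the fit with the Y-linked covariate and the exact test of list means were chosen after seeing the data. The total of 1650 genes stayed within 1.5 times under every alternative except the stricter filter, with 1378 to 1535 when 1 library was left out, 1668 with median centring and 1531 with the Y-linked covariate. No named gene changed sign past the threshold. Of 1598 recomputed differences of 96 named genes, 1582 kept their side of the threshold, 5 lost it and 11 gained it. The stricter filter tested 1519 genes and gave 737 calls, 380 higher and 357 lower, 22 of them with a difference of at least 1, and 4 lists; fewer tested genes explain the lower gene counts, since all 683 of the main calls it tested were kept, while 3 lists that could still be tested no longer passed. Without a filter 18 lists passed: of the lists added, 4 had already been tested (resting Tregs, TNF receptor family, glycolysis and immediate early genes) and 3 had too few tested genes before. On log2 normalised reads 739 genes differed by at least 1, of which 222 were among the 5261 genes and the rest came from the wider filter. With an estimated correlation 3 lists passed.

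Other divisions of the 8 libraries into 4 and 4 bear on whether chance can be excluded. For each count of genes past the threshold, total, higher, lower and with a difference of at least 1, the real division was the only 1 of 35 with a count as large, with highest other values of 1, 1, 1 and 0. For gene lists, 4 of the 35 divisions gave as many as the 11 observed, with a highest other value of 14, so chance cannot be excluded for the number of lists. An exact permutation of each list's mean value passed 13 lists, each with the smallest exact p and an adjusted p of 0.044. No paired analysis was possible because the groups share no replicate numbers. Depth limits the genes below 206 normalised reads, which the main filter leaves out.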

Other observations

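The families and genes below were chosen after their values were seen, so their p-values describe them and do not test them. Several further families held more rises than falls, most of them without passing when the correlation was estimated. Subunits of translation initiation factor 3, a family narrowed from all initiation factors after a first result was seen, rose in 11 of 13 tested genes (camera adjusted p = 8.19e-06, and adjusted p = 0.0183 with an estimated correlation), with Eif3b at 1613 ± 56.6 normalised reads against 1023 ± 122. Chaperonin and heat shock protein genes rose in 13 of 18 with 0 falling (adjusted p = 8.19e-06, and adjusted p = 0.102 with an estimated correlation), among them the chaperonin subunit Cct3 at 1075 ± 70.6 against 655 ± 63.6. Aminoacyl-tRNA synthetase genes rose in 7 of 15 with 0 falling (adjusted p = 0.00508, and adjusted p = 0.102 with an estimated correlation). Without IL-2 library 44 only 3 of the 15 rose. That library did not carry the rise, since its summed normalised count was the lowest of its group (8200 against 8364 to 9320). Proteasome subunits rose in 14 and fell in 1 of 36 (adjusted p = 6.42e-04, and adjusted p = 0.102 with an estimated correlation). Histone genes rose in 27 and fell in 1 of 39 (adjusted p = 5.44e-08, and adjusted p = 0.272 with an estimated correlation). IL-2 library 44 was the highest of its group for 38 of the 39, with a summed normalised count of 52761 against 25635 to 27827 in the other 3, and without it 25 still rose. Of 10 S100 and annexin genes, 6 rose and S100a11 fell (adjusted p = 0.00343, and adjusted p = 0.182 with an estimated correlation), with S100a6 at 1353 ± 352 against 456 ± 32.0 and Anxa2 at 1064 ± 384 against 334 ± 46.5, both highest in library 44. Histone and S100 genes have near-identical relatives whose reads can be divided wrongly.

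Guanylate-binding and immunity-related GTPase genes, which interferon induces, fell in 10 and rose in 2 of 19 (adjusted p = 4.04e-04, and adjusted p = 0.176 with an estimated correlation). Without IL-2 library 44, 10 fell and 1 rose. Gbp6 went from 1141 ± 146 in controls to 458 ± 74.5, Gbp10 from 428 ± 72.7 to 106 ± 12.3 and Irgm1 from 708 ± 116 to 330 ± 57.3, while Gbp3 rose from 1621 ± 89.4 to 2191 ± 127 and Gbp7 also rose.

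A group of transcripts that were almost absent from control Tregs reached at least 600 ± 64.0 normalised reads with IL-2, the value of Syk. Drc1, a gene of the ciliary dynein regulatory complex, went from 35.3 ± 5.20 to 917 ± 84.1, beside the dynein gene Dnah7a. The transcript of Gldc, which encodes a glycine-cleaving enzyme, went from 7.26 ± 14.5 to 637 ± 110, that of the actin regulator Enah from 12.8 ± 9.69 to 811 ± 273 and that of Nav1 from 20.3 ± 14.5 to 669 ± 92.3. The kinase gene Syk, best known from B and myeloid cells, started from 24.5 ± 8.63. In the other direction, the activation marker Cd83 went from 310 ± 117 to 25.6 ± 15.8, the oxidase gene Cybb from 362 ± 48.2 to 36.3 ± 20.1, Slc28a2b from 576 ± 84.9 to 61.3 ± 24.1 and Ccr6 from 217 ± 48.2 to 26.5 ± 16.9. Cd4 itself went from 4136 ± 300 to 2523 ± 354 (limma adjusted p = 1.49e-04). Like Cd83 and Cybb, the myeloid markers Lyz2 and C1qa fell, from 10.1 ± 4.64 and 8.94 ± 7.73 to 0. Both passed limma without a filter (adjusted p = 0.00131 and 0.00923). H2-Aa also passed that fit, falling from 15.4 ± 9.29 to 2.20 ± 2.74 (adjusted p = 0.0298). Mpeg1, H2-Ab1 and H2-Eb1 did not pass it (adjusted p = 0.433, 0.880 and 0.237). Which cells the Cd83 and Cybb reads came from was not tested.

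Y-linked transcripts divided the libraries across the groups. Ddx3y had 0 normalised reads in IL-2 libraries 41 and 42 and in control library 45, which allows up to 3 reads each, and 345, 397, 216, 362 and 460 in IL-2 libraries 43 and 44 and control libraries 46, 47 and 48. The labels give no sex for these samples. With the presence of Ddx3y as a covariate, 1531 genes passed, and 1468 of the 1650 main calls passed in the same direction, so an unequal mix of sexes is unlikely to account for most calls.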
